A study of Homo sapiens with 12 samples.

How the data were processed

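RNA was sequenced from HL-60 cells, an established human promyelocytic leukaemia line, of wild-type genotype. Per the labels' protocols, cells were plated in duplicate in 6-well plates at 100000 cells per mL and received either decitabine at 100 nM, added at 0, 24 and 48 h, or its vehicle DMSO. Decitabine is a cytidine analogue that is built into DNA and traps DNA methyltransferases. RNA was taken at 6, 72 and 120 h, depleted of ribosomal RNA with RiboZero Gold and turned into stranded libraries with the ScriptSeq v2 kit, which were read as single-end 50 bp reads on an Illumina HiSeq, per the labels' protocols. The labels list 12 samples in 6 groups of 2. The duplicates were wells of one line, and nothing says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

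The deposited table listed 60240 genes by Ensembl identifier and symbol. The submitters' processing notes name the hg38 genome, Salmon 1.2.1, STAR, featureCounts, DESeq2 and limma, with no role or order, and the annotation release is not given in the sources used here. The deposited values are a normalised signal that is never negative. In their low range, 59.3 to 65.3% of the values of a library were whole multiples, within 0.01, of a step of that library's own. These are the properties of estimated counts that were divided by a size factor per library, and whole reads could not be recovered for nearly all genes, so no count model was run. From the steps, the depth was estimated at 14427331 to 32908419 counts per library, and the normalised totals were 12815698 to 15959030. A single count was worth between 0.407 and 0.961 normalised units. The column heading names 12 libraries, per the file headers, whereas each gene carries 11 values after its identifier and symbol. The heading was read as starting at the symbol, which gives the first 11 library names a value each and leaves DMSO 72 h replicate 2 without values. That library was not analysed here. In this reading, libraries of one group differed by a mean of the median absolute log2 differences of 0.299, against 0.439 between groups. Read from the identifier instead, these were 0.429 and 0.426. Every result rests on this reading of the heading.

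Values were transformed to log2(value + 1), and genes with at least 10 in at least 2 libraries were kept, which left 16152. A fold change is therefore on the log2(value + 1) scale and understates the change of low genes. Where all libraries of a group were at 0, the gene is said to be listed at 0 and no fold or difference of folds is given, although such genes enter the medians of lists. A linear model with 1 mean for each of the 6 groups was fitted to all 11 libraries with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3. It had 5 residual degrees of freedom, or 8.4 with those limma borrowed across genes. The design, written for 12 libraries, was otherwise kept. DMSO at 72 h had 1 library, which was assumed to vary like the other groups, so its value has no SD. Decitabine was compared with DMSO at each time, these effects were compared between times, and DMSO cells at 72 and 120 h were compared with DMSO cells at 6 h. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. In the text, values of a group are means of normalised counts ± SD with n = 2 unless stated. Plots were drawn with matplotlib 3.10.9.

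A total of 34 gene lists with 863 genes was fixed before the data were examined, as were the comparisons, the filter, the pseudocount, the rule for naming genes and most of the alternatives. The lists held cancer-testis antigens, germ-cell and meiosis genes, interferon-stimulated genes, nucleic-acid sensors, MHC class I and class II presentation, primary granule, late neutrophil, monocyte and macrophage, erythroid and megakaryocyte, and eosinophil, basophil and mast cell genes. Others held myeloid transcription factors, lymphoid genes, epithelial, stromal and endothelial genes, HOXA and HOXB genes, DNA replication, mitotic, replication-dependent histone, p53 target, DNA repair and checkpoint, and apoptosis genes. The remainder were the DNA methylation machinery, decitabine uptake and metabolism, mRNA decapping and 5-prime decay, m6A factors, imprinted genes, inflammatory NF-kB targets, integrated stress and unfolded protein response, cholesterol synthesis, ribosomal proteins, mitochondrially encoded mRNAs, abundant structural RNAs, immune ligands and checkpoints, and endogenous-retrovirus-derived genes. With at least 3 tested members, 32 lists entered limma's camera test, two-sided, with a preset correlation of 0.01, adjusted over the 96 tests of 32 lists and 3 treatment comparisons. Members under the filter were not tested. Members were counted as risen or fallen by the adjusted p over all genes, and again adjusted over the list alone.

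Named genes were those with the 6 highest and 6 lowest called log2 fold changes per treatment comparison, with a mean of at least 50 in the higher group and both decitabine libraries on the same side of the DMSO libraries. To these came up to 2 called members of each list with the smallest adjusted p, 10 genes fixed in advance (DNMT1, DNMT3A, DNMT3B, DCK, ITGAM, CD14, MPO, ELANE, MYC and CDKN1A) and the 3 largest called differences between times. This gave 84 genes, some of which are not reported here. Other list members are given as examples and were chosen after their values were seen. Gene coordinates were taken from GENCODE 29 on GRCh38, in which 15879 of the tested genes (98.3%) had a match by identifier. In the deposited table, 33 symbols stood on more than 1 line.

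The procedure was tested on simulated data with 200 changed genes per comparison. Of genes changed 4-fold, 55.0% were recovered at 6 h among 14840 genes, 53.5% at 72 h among 14831 and 70.0% at 120 h among 14842. Of genes changed 2-fold, 12%, 8.0% and 24.0% were recovered at those times. With no change simulated, 0 genes were called in each of the 8 comparisons. The wider distance of the decitabine 72 h pair (median absolute log2 difference 0.59, against 0.19 to 0.26 in the other pairs) was not simulated. The simulated rates may therefore not hold for comparisons with 72 h. Where genes were changed, 9.5% of the calls at 6 h, 7.6% at 72 h and 4.1% at 120 h were unchanged genes. Alternatives were other pseudocounts, filters, scalings and estimates of the spread, a fold threshold, a replicate block and each library left out in turn, and for lists an estimated correlation and limma's fry. Sample weights, a GC correction, a comparison of decitabine at 72 h with all 5 DMSO libraries, list tests without decitabine 72 h replicate 2 and, at 6 h, without each 6 h library, list tests with no filter on low values, separate fits of 72 and 120 h for their overlap, and list tests of culture time and of differences between times were added after seeing the data.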

Results

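Gene expression was measured in HL-60 cells at 6, 72 and 120 h after decitabine was first added, beside DMSO controls of the same age, in order to follow the response to this DNA hypomethylating drug over time. HL-60 is a promyelocytic leukaemia line that can be driven towards granulocytes or monocytes in culture. Values were analysed for 11 libraries, 2 for each group except DMSO at 72 h, which had 1, since the heading of the deposited table names 12 libraries over 11 columns of values and was read as starting at the gene symbol. Estimated depth ran from 14427331 counts in DMSO 6 h replicate 1 to 32908419 in decitabine 6 h replicate 2. Of the 60240 genes, 20846 were at 0 in every library and 16152 were tested. The decitabine 72 h libraries lay farther apart from one another than any other pair, with a median absolute log2 difference between them of 0.59 against 0.19 to 0.26 in the other pairs. At 120 h and in decitabine 72 h replicate 1, the transcript FP671120.7 took 3.89 to 10.86% of all counts and mitochondrial mRNAs 0.662 to 0.812%. In the other 6 libraries, which include decitabine 72 h replicate 2, these shares were 0.04 to 0.79% and 0.238 to 0.415%. All p-values below measure the spread between these wells and libraries and not between separate experiments.

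At 6 h, no single gene was called different between decitabine and DMSO. MYC, a transcription factor that drives growth, stood at 14890 ± 1001 with decitabine and 13960 ± 493 with DMSO (normalised counts, SD, n = 2). DNMT1, the maintenance DNA methyltransferase that decitabine traps, stood at 5441 ± 1529 and 6380 ± 134. CDKN1A, which encodes the cell cycle inhibitor p21, stood at 13.97 ± 2.73 and 11.9 ± 0.773. Limma called 0 of 16152 genes, with a smallest adjusted p of 0.257, and 541 genes had an unadjusted p under 0.05. Other settings called 3 genes (limma without a trend) or 1 (limma with the spread of these libraries alone), and without decitabine 6 h replicate 2 limma called 3. Without DMSO 6 h replicate 2, and without decitabine 72 h replicate 1, limma called 1. In simulated data, whose spread may not match that of the 6 h libraries, 55.0% of genes changed 4-fold and 12% of those changed 2-fold were recovered at this time.

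At 6 h camera called 4 gene lists, and each call was lost without at least 1 of the 6 h libraries. All 13 mitochondrially encoded mRNAs, which carry subunits of the respiratory chain, had negative log2 fold changes, with a median of -0.41 and a camera adjusted p = 0.00253 (adjusted p = 0.593 with an estimated correlation). The replicates went apart, since these mRNAs took 0.238% of counts in decitabine replicate 1 and 0.415% in replicate 2, against 0.379 and 0.382% with DMSO. Without decitabine 6 h replicate 1, 9 of 13 were negative, with a median of -0.11 (camera adjusted p = 0.453). Of 18 integrated stress and unfolded protein response genes, 15 were positive, and the list was higher (median 0.15, camera adjusted p = 0.0293, adjusted p = 0.2 with an estimated correlation). Its camera adjusted p was 0.346 without decitabine 6 h replicate 2, 0.251 without DMSO 6 h replicate 2 and 0.0593 without the filter on low values. The DNA repair and checkpoint list was lower, with 6 of 25 members positive (camera adjusted p = 0.0469, adjusted p = 0.535 with an estimated correlation and 0.188 with quantile normalisation). Its camera adjusted p was 0.0543 without decitabine 6 h replicate 1, 0.201 without its replicate 2 and 0.255 without DMSO 6 h replicate 1. The interferon-stimulated list was higher, with 20 of 28 members positive (median 0.15, camera adjusted p = 0.0486, adjusted p = 0.431 with an estimated correlation). The interferon call was also lost with quantile normalisation (camera adjusted p = 0.122), without decitabine 72 h replicate 2 (0.0628), without decitabine 6 h replicate 2 (0.376), without DMSO 6 h replicate 1 (0.549) and without the filter (0.189). No member of any list was called over all genes, and adjusted over the list alone 1 lymphoid gene was lower. The camera adjusted p of the other 28 lists ran from 0.066 for p53 targets to 0.899 for cancer-testis antigens. Median and mean differed in sign for the DNA replication, apoptosis, eosinophil and epithelial lists. The germ-cell list, at a median of -0.38 and a camera adjusted p of 0.108, was called lower with quantile normalisation (0.0452).

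By 72 h, decitabine had raised some genes that are normally restricted to the germ line, together with some genes of eosinophils and neutrophils, whereas MYC and IRF8 had fallen. EPX, the peroxidase of eosinophil granules, rose from 68.3 in the DMSO library to 1007 ± 336 (SD, n = 2). DCAF4L1 rose from 1.49 to 520 ± 170 and the testis histone gene H1-6 from 0.997 to 429 ± 21.7. MYC fell from 11410 to 3356 ± 730. IRF8, a transcription factor that directs monocyte fate, fell from 949 to 337 ± 59.8. Limma called 303 genes higher and 50 lower, which is 2.2% of those tested, and 293 and 46 of them changed at least 2-fold. The log2 fold change was 3.82 for EPX, 7.67 for DCAF4L1 (chromosome 4, 41981696 to 41986467), -1.78 for MYC (chromosome 8, 127735434 to 127741434) and -1.50 for IRF8 (chromosome 16, 85898803 to 85922609), at limma adjusted p of 0.00263, 0.00127, 0.00776 and 0.0125. DCAF4L1 stood at 7.98 to 14.5 in the other 4 DMSO libraries, and its log2 fold change against all 5 DMSO libraries was 5.81.

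Of the 35 genes of the germ-cell and meiosis list, 13 passed the filter on low values, and of these 5 rose at 72 h, 11 adjusted over the list alone. Its median log2 fold change was 2.51 and its camera adjusted p = 2.7e-09, which held with an estimated correlation (0.0252). Of the 13, 4 were under 10 in all DMSO libraries and could enter the test only through their decitabine libraries. Without the filter, 4 of 32 members above 0 rose and 1 fell (median 1.06, camera adjusted p = 5.97e-07, adjusted p = 0.0362 with an estimated correlation). DAZL, an RNA-binding protein of germ cells, rose from 0.887 to 58.8 ± 19.6, and MAEL, a piRNA pathway protein, from 0.414 to 111 ± 24.8, with log2 fold changes of 4.95 and 6.29. Of 57 cancer-testis antigens, 9 passed the filter, 7 of them under 10 in all DMSO libraries, and 4 rose, 6 adjusted over the list alone (median 3.94, camera adjusted p = 8.39e-05, adjusted p = 0.0744 with an estimated correlation). Without the filter, 6 of 37 members above 0 rose (median 0.63, camera adjusted p = 5.52e-08, adjusted p = 0.0193 with an estimated correlation). MAGEB2 rose from 2.99 to 132 ± 2.05, and PAGE2B, which has the near-identical copy PAGE2 and is therefore uncertain, was listed at 0 in the DMSO library and stood at 21.7 ± 7.67 with decitabine. PNMA5 was listed at 0 in the DMSO library and stood at 446 ± 95.3 (limma adjusted p = 0.00131). FAM9C rose from 6.05 to 1443 ± 857 and the collagen gene COL14A1 from 1.86 to 342 ± 77.2. TKTL1, a transketolase-like gene, was listed at 0 and stood at 85.5 ± 3.35. The histone genes H2AC14 and H3C3, listed at 0 in the DMSO library, stood at 258 ± 32.6 and 217 ± 158, and histone genes share reads with close copies. The PAGE2B call was lost without decitabine 120 h replicate 2 (limma adjusted p = 0.0536).

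The eosinophil list also rose at 72 h, as did single genes of the neutrophil and monocyte lists. In the eosinophil, basophil and mast cell list, 7 of 13 members rose, 9 adjusted over the list alone, with a median of 2.31 and a camera adjusted p = 2.7e-09 (adjusted p = 0.0252 with an estimated correlation). Of the 13, 4 were under 10 in all DMSO libraries. Without the filter on low values, 6 of 16 rose (median 2.03, camera adjusted p = 7.31e-11, adjusted p = 0.0185 with an estimated correlation). PRG2, the major basic protein of eosinophils, rose from 16510 to 74740 ± 10020, a log2 fold change of 2.17. In the late neutrophil list, 5 of 33 rose, and 13 rose and 1 fell adjusted over the list alone (median 0.83, camera adjusted p = 0.000173, adjusted p = 0.192 with an estimated correlation). Of the 33, 5 were under 10 in all DMSO libraries, and without the filter 4 of 35 rose. The calcium-binding S100A12 rose from 531 to 1557 ± 105. In the monocyte and macrophage list, 3 of 17 rose and 1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.01, adjusted p = 0.295 with an estimated correlation). CLEC7A, the receptor for beta-glucans, rose with a log2 fold change of 2.66, while CCR2, a chemokine receptor of monocytes, fell by 1.63 on the log2 scale. The CCR2 call was lost without DMSO 6 h replicate 2 (limma adjusted p = 0.0511). MS4A6A fell from 148 to 15.6 ± 2.20 and PALD1 from 154 to 33.2 ± 17.6. NTHL1, a DNA glycosylase, fell from 70.9 to 15.2 ± 4.19. The calls of PALD1 and NTHL1 were lost in 8 and 4 of 10 fits with 1 library left out.

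Of the 6 lowest genes at 72 h, AVIL and BCAS3 stood far higher in the lone DMSO library than in the other DMSO libraries. AVIL stood at 145 in it against 1.32 to 3.79 in the other 4 DMSO libraries, and with decitabine at 9.11 ± 4.13. BCAS3 stood at 244 against 40.9 to 59.4, and with decitabine at 45.9 ± 7.58. Of the genes called higher, 19 of 303, and of those called lower, 4 of 50, lay where this library was over 2-fold beyond the other 4 DMSO libraries. CU633967.1 fell from 71.3 to 8.71 ± 0.707, although DMSO libraries of other times ranged from 22.5 to 64.8. Calls of AVIL and CU633967.1 were each lost in 6 of 10 fits with 1 library left out.

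Inflammatory and immune lists shifted at 72 h as well. Of 21 inflammatory NF-kB targets, 5 rose, and 12 rose and 1 fell adjusted over the list alone, with a median of 1.27 and a camera adjusted p = 4.53e-07 (adjusted p = 0.0333 with an estimated correlation). Of the 21, 4 were under 10 in all DMSO libraries, and without the filter on low values 3 of 25 rose (median 1.19). CCL2, a chemokine that attracts monocytes, rose from 36.5 to 281 ± 118, and BCL2A1, an anti-apoptotic member of the BCL2 family, from 107 to 337 ± 28.1. In the interferon-stimulated list, LAMP3 rose among 28 members, with 3 adjusted over the list alone (median 0.67, camera adjusted p = 0.00062, adjusted p = 0.234 with an estimated correlation). HLA-E rose among 18 MHC class I members, with 4 adjusted over the list alone (camera adjusted p = 0.0231, adjusted p = 0.295 with an estimated correlation). Without the filter on low values, 0 of 19 members were called singly. Among 7 tested of 20 lymphoid genes, CD3D and GNLY rose, with 3 adjusted over the list alone (median 1.44, camera adjusted p = 0.00315, adjusted p = 0.147 with an estimated correlation). Of the 7, 4 were under 10 in all DMSO libraries, CD3D and GNLY among them, and could enter the test only through their decitabine libraries. Without the filter, 2 of 17 rose (median 0.92). LUM rose among 6 tested of 18 epithelial and stromal genes, with 2 adjusted over the list alone (median 1.43, camera adjusted p = 0.0342, adjusted p = 0.234 with an estimated correlation). That list was not called with quantile normalisation (camera adjusted p = 0.0573), without decitabine 72 h replicate 2 (0.0945) or without the filter on low values (0.153). The calls of LAMP3 and LUM were lost in 2 and 5 of 10 fits with 1 library left out.

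Ribosomal protein genes were lower as a list at 72 h, with a median of -0.28 over 76 members, none of which was called singly (camera adjusted p = 0.00093, adjusted p = 0.463 with an estimated correlation and 0.191 without decitabine 72 h replicate 2). Outside the called lists, BTG2 and TP53INP1 of the p53 target list rose with log2 fold changes of 2.46 and 3.12. The histone genes H1-1, H2BC3 and H4C4 rose, while the histone list had a median of -0.43, a mean of 0.17 and a camera direction of lower (adjusted p = 0.34). GATA1, which directs erythroid, megakaryocyte and eosinophil fates, was listed at 0 in DMSO and stood at 44.9 ± 14.99. ITGA2B, TLR8 and ERV3-1 were called higher with log2 fold changes of 2.33, 1.34 and 1.38. Their calls were lost in 9, 8 and 9 of 10 fits with 1 library left out, and that of GATA1 in 4. Over all alternatives, these calls were lost 18, 11 and 16 times, and that of GATA1 8 times. Mitochondrial mRNAs had a median of 0.92 (camera adjusted p = 0.0768), and were called higher without decitabine 72 h replicate 2 (1.78e-07). That call sets replicate 1, with FP671120.7 at 5.25% of counts, against the DMSO library, with 0.09%, so the treatment and the split of the libraries by this transcript cannot be told apart in it. The primary granule list was not called with both decitabine 72 h libraries (camera adjusted p = 0.189). Without replicate 2 camera called it higher, but this too compares 1 library from each side of that split.

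The counts at 72 h moved with single libraries. The numbers of genes that limma called higher and lower were 130 and 13 without decitabine 120 h replicate 1 and 133 and 13 without its replicate 2, 210 and 21 without DMSO 120 h replicate 1 and 213 and 20 without its replicate 2. They were 193 and 15 without decitabine 6 h replicate 1, 195 and 15 without its replicate 2, and 176 and 13 without either DMSO 6 h library. Without decitabine 72 h replicate 1 they were 2689 and 2070, and without its replicate 2, 457 and 269, which takes the distance within this pair out of the shared estimate of the spread. With the spread of the 72 h libraries alone, on 1 residual degree of freedom, limma called 0 genes while 766 had an unadjusted p under 0.05, and with sample weights it called 75 and 5. The share of higher genes among those called was 85.8%. It was 74.5% with quantile normalisation, 75.3% with the GC correction, 59.6% without the filter on low values and 59.3% against all 5 DMSO libraries, and 56.5 to 93.1% over the left-out libraries, with 56.5 and 62.9% without decitabine 72 h replicates 1 and 2.

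At 120 h decitabine raised 10 of 13 eosinophil, basophil and mast cell genes and 21 of 33 late neutrophil genes and lowered MYC and IRF8. EPX rose from 87.8 ± 6.71 with DMSO to 5637 ± 78.5 with decitabine (SD, n = 2), 63.6-fold. S100A12 rose from 523 ± 21.6 to 3977 ± 140. MYC fell from 13640 ± 768 to 3239 ± 291, and IRF8 from 1019 ± 15.6 to 184 ± 10.8. Limma called 1601 genes higher and 969 lower, 15.9% of those tested, of which 1326 and 485 changed at least 2-fold. The log2 fold changes were 5.99 (SE 0.284) for EPX, 2.92 (0.143) for S100A12, -2.08 (0.185) for MYC and -2.47 (0.173) for IRF8, at limma adjusted p of 4.74e-05, 4.74e-05, 0.000342 and 0.000119.

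**Figure D1:**
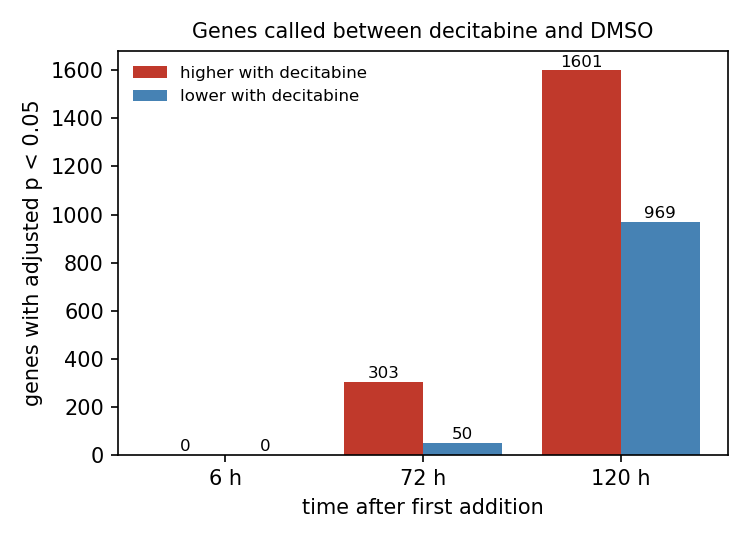
Number of genes called higher and lower with decitabine than with DMSO at 6, 72 and 120 h after the first addition (limma, adjusted p under 0.05, 16152 genes tested). No gene was called at 6 h, 303 were higher and 50 lower at 72 h, and 1601 were higher and 969 lower at 120 h.

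**Figure D2:**
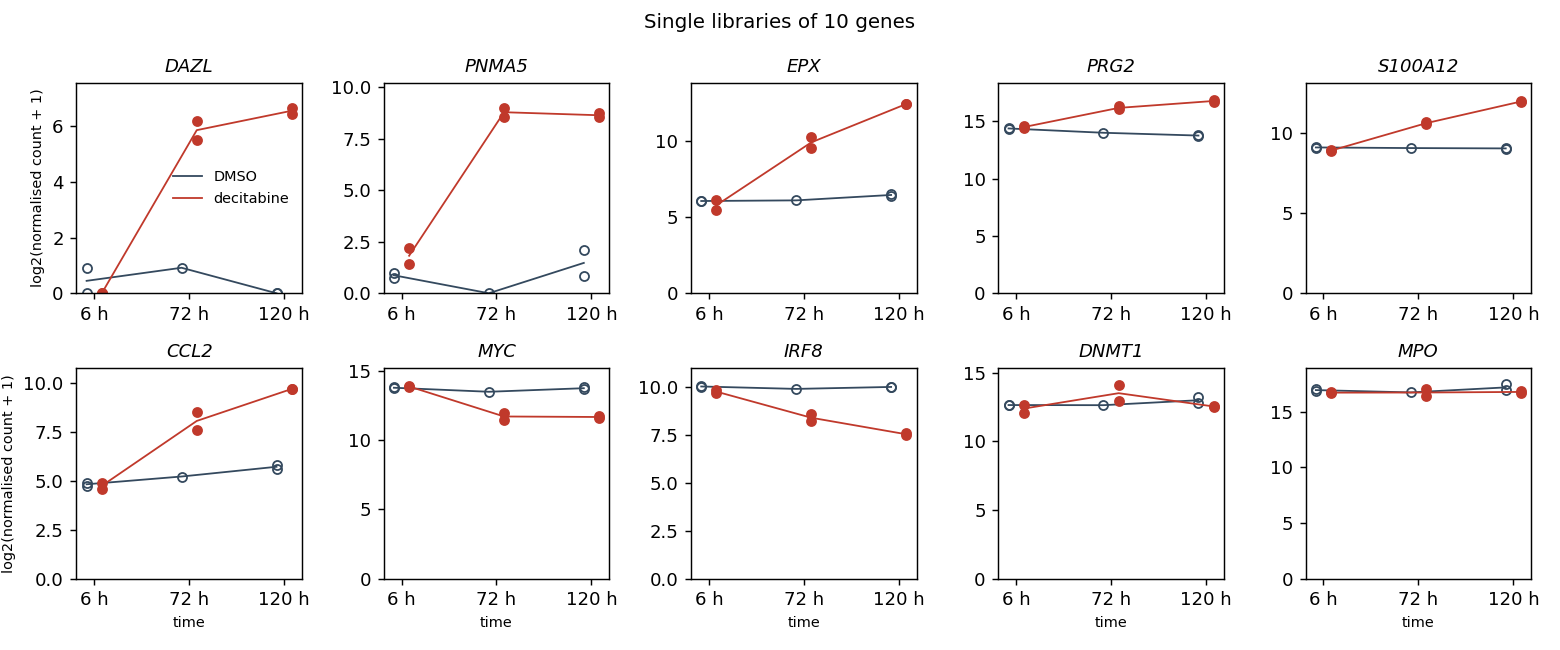
Expression of 10 genes, as log2(normalised count + 1), against time after the first addition, with a point for each library (open blue, DMSO; red, decitabine) and lines through the group means. EPX, PRG2 and S100A12 lay above DMSO at 72 and 120 h and MYC and IRF8 below, while DNMT1 and MPO were not called at any time.

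The eosinophil, basophil and mast cell list was among the most changed at 120 h. Of its 13 members, 10 rose over all genes and adjusted over the list alone, with a median of 3.85 and a camera adjusted p = 1.47e-09, which held with an estimated correlation (0.0252). PRG2 rose from 13950 ± 730 to 113300 ± 7298, 8.11-fold. IL5RA, the interleukin-5 receptor chain, CLC, which forms Charcot-Leyden crystals, and HDC, the histamine-forming decarboxylase, rose with log2 fold changes of 6.23, 6.76 and 6.41. The basophil and mast cell factor GATA2 rose by 1.88. In the late neutrophil list, 21 of 33 rose and 1 fell, or 26 and 3 adjusted over the list alone, with a median of 2.30 and a camera adjusted p = 2.78e-12 (adjusted p = 0.041 with an estimated correlation). MMP9, S100A8 and the oxidase subunit CYBB rose with log2 fold changes of 6.78, 2.66 and 1.90, whereas the collagenase MMP8 fell by 2.50. ITGAM, the integrin CD11b, rose from 269 ± 83.3 to 1227 ± 133 (log2 fold change 2.21, limma adjusted p = 0.000833). In the primary granule list, 7 of 15 rose, and 9 rose and 1 fell adjusted over the list alone (median 0.89, camera adjusted p = 0.00446, adjusted p = 0.407 with an estimated correlation). BPI, a bactericidal protein, rose 4.88-fold and the ribonuclease RNASE2 5.19-fold. MPO and ELANE, the peroxidase and elastase of primary granules, were not called, with log2 fold changes of -0.41 and -1.13 (limma adjusted p = 0.383 and 0.102).

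Monocyte genes and transcription factors also shifted at 120 h. In the monocyte and macrophage list, 10 of 17 rose and 2 fell, or 12 and 2 adjusted over the list alone (median 1.75, camera adjusted p = 0.000248, adjusted p = 0.192 with an estimated correlation). CLEC7A rose from 28.2 ± 1.85 to 320 ± 39.4, and CD14, the co-receptor for lipopolysaccharide, from 26.8 ± 6.57 to 118 ± 8.28. CCR2 fell from 181 ± 17.6 to 25.8 ± 4.05. The call of CD14 was lost in 5 of 11 fits with 1 library left out. Of 24 myeloid transcription factors, 9 rose and 2 fell, or 12 and 2 adjusted over the list alone (median 0.95, camera adjusted p = 0.00852, adjusted p = 0.378 with an estimated correlation). Those that rose included EGR2 and JUN, at log2 fold changes of 4.51 and 2.30, and those that fell were MYC and IRF8. GATA1 was listed at 0 in DMSO and stood at 80.8 ± 0.974. The platelet integrin gene ITGA2B rose from 17.9 ± 4.86 to 349 ± 4.32. These 2 rose and the transferrin receptor TFRC fell among 6 tested of 22 erythroid and megakaryocyte genes, over all genes and adjusted over the list alone (camera adjusted p = 0.255). P2RY14, a receptor for nucleotide sugars, was listed at 0 in DMSO and stood at 92.3 ± 22.4.

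Germ-line genes were also among those raised at 120 h. Of the 13 germ-cell and meiosis genes tested, out of 35 listed, 8 rose, 9 adjusted over the list alone, with a median of 2.88 and a camera adjusted p = 9.17e-07 (adjusted p = 0.0366 with an estimated correlation). Of the 9 cancer-testis antigens tested, out of 57 listed, 6 rose by either adjustment, that is over all genes and adjusted over the list alone (median 3.74, camera adjusted p = 0.00012, adjusted p = 0.0744 with an estimated correlation). Without the filter on low values, 8 of 32 and 10 of 37 members above 0 rose, with medians of 1.29 and 0.83 (camera adjusted p = 3.06e-07 and 8.68e-07, or 0.0362 and 0.0213 with an estimated correlation). DAZL was listed at 0 in DMSO and stood at 93.6 ± 10.2, and PAGE2B, also listed at 0, at 57.9 ± 1.92. MAEL rose from 1.96 ± 0.0563 to 116 ± 3.52 and MAGEB2 from 6.02 ± 1.73 to 92.0 ± 12.9. The 6 highest genes by the naming rule were COL14A1 (chromosome 8, 120059780 to 120372036), FAM9C (X, 13035618 to 13044682), H3C3, TKTL1, GNLY and PNMA5 (X, 152988824 to 152994127). COL14A1 rose from 1.58 ± 0.968 to 821 ± 48.5 and FAM9C from 11.5 ± 9.19 to 3330 ± 226, with log2 fold changes of 8.36 and 8.28. PNMA5 rose from 2.03 ± 1.73 to 399 ± 34.4. Of the 949 tested genes under 10 in all DMSO libraries, 332 were called higher at 120 h, 20.7% of all those called higher, and 97 at 72 h, 32.0%. These genes could enter the test only through their decitabine libraries. They included 4 of the 7 tested lymphoid genes and 4 of the 13 eosinophil, basophil and mast cell genes. Of the 21 NF-kB targets they included 4, and of the 33 late neutrophil genes 5. The counts and medians of these lists rest in part on such members.

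Inflammatory NF-kB targets and part of the MHC class I list rose at 120 h, while the class II chaperone gene CD74 fell. Of 21 inflammatory NF-kB targets, 17 rose, and 19 rose and 1 fell adjusted over the list alone, with a median of 2.24 and a camera adjusted p = 9.64e-10 (adjusted p = 0.0252 with an estimated correlation). CCL2 rose from 52.1 ± 5.94 to 836 ± 5.88, 15.8-fold, and the cytokine genes IL1B and CXCL8 by 3.73 and 2.24 on the log2 scale. In the MHC class I list, 9 of 18 rose, 11 adjusted over the list alone (median 0.94, camera adjusted p = 0.000105, adjusted p = 0.135 with an estimated correlation). HLA-C rose from 2866 ± 262 to 8125 ± 213, and B2M, the shared light chain, by 1.01 on the log2 scale, where HLA genes share reads with one another. Of the class II list 2 genes were tested, of which CD74, the invariant chain, fell from 243 ± 31.0 to 121 ± 9.23 and the other was not called. In the interferon-stimulated list, 4 of 28 rose, 9 adjusted over the list alone (median 0.59, camera adjusted p = 0.0486, adjusted p = 0.431 with an estimated correlation and 0.114 with quantile normalisation). LGALS3BP and LAMP3 rose 24.7-fold and 7.10-fold. Of 17 nucleic-acid sensors, 5 rose and the nuclease gene TREX1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.416), with TLR8 at 753 ± 15.3 against 111 ± 1.94 and the inflammasome sensor AIM2 at 84.7 ± 0.479 against 2.97 ± 3.43. Of 8 immune ligands and checkpoints, VSIR rose and LGALS9 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.34). The calls of CD74 and VSIR were lost in 6 and 8 of 11 fits with 1 library left out.

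**Figure D3:**
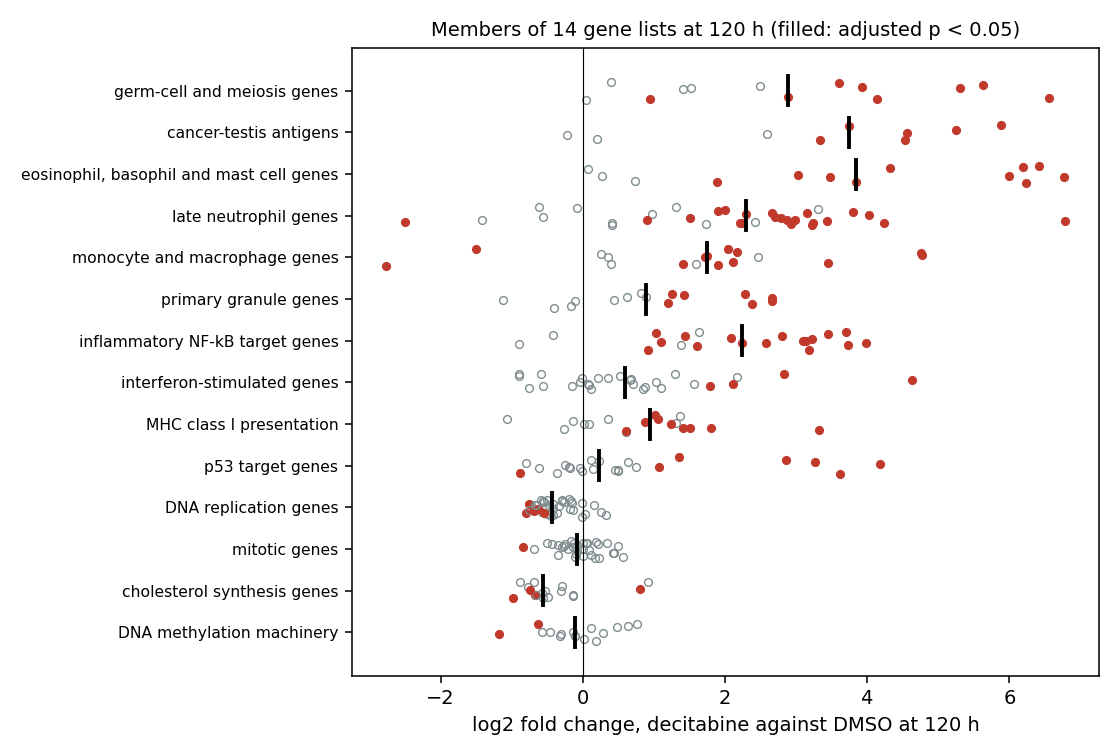
Log2 fold change of decitabine against DMSO at 120 h for each tested member of 14 gene lists (dots; filled, limma adjusted p under 0.05), with the median of each list as a black bar. The median was 3.85 for the eosinophil, basophil and mast cell list, 2.30 for the late neutrophil list, 2.24 for NF-kB targets and -0.43 for DNA replication genes.

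Of the p53 target list, CDKN1A, BTG2 and TP53INP1 rose at 120 h, and 5 of 38 DNA replication genes fell. Whether p53 itself was active was not tested. CDKN1A rose from 12.5 ± 2.05 to 95.9 ± 3.95 (log2 fold change 2.85, limma adjusted p = 0.004), BTG2, an antiproliferative factor, 9.58-fold and TP53INP1 12.3-fold. Of 23 p53 targets, 6 rose and 1 fell, or 7 and 2 adjusted over the list alone (median 0.23, camera adjusted p = 0.108). Of 29 apoptosis genes, 5 rose, and 6 rose and 1 fell adjusted over the list alone (median 0.44, camera adjusted p = 0.106), among them the anti-apoptotic BCL2A1, at 697 ± 19.8 against 99.2 ± 12.5. Of 38 DNA replication genes, 5 fell by either adjustment, over all genes and adjusted over the list alone, with a median of -0.43 (camera adjusted p = 2.12e-05, adjusted p = 0.268 with an estimated correlation). RFC3, a clamp loader subunit, fell from 1208 ± 39.7 to 751 ± 8.19 and GINS1, of the replicative helicase, from 1107 ± 3.61 to 655 ± 49.1. Of 25 DNA repair and checkpoint genes, 3 fell by either adjustment, over all genes and adjusted over the list alone (median -0.28, camera adjusted p = 0.0125, adjusted p = 0.431 with an estimated correlation and 0.105 with quantile normalisation), among them PARP1 and ATR. PLK1, a mitotic kinase, fell from 486 ± 12.7 to 271 ± 3.31 among 33 mitotic genes, with none adjusted over the list alone (camera adjusted p = 0.423). In the histone list, 3 of 32 rose by either adjustment, over all genes and adjusted over the list alone, with a median of -0.13, a mean of 0.06 and a camera direction of lower (adjusted p = 0.583). These were H1-1, H2BC3 and H4C4. The calls of RFC3, GINS1, ATR, PARP1 and PLK1 were each lost in 4 of 11 fits with 1 library left out.

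The mRNAs of enzymes that decitabine acts on or that process it showed few calls at 120 h, and protein was not measured. DNMT1 stood at 5937 ± 88.8 against 8241 ± 1819, and DNMT3A, DNMT3B and the activating kinase gene DCK had log2 fold changes of 0.76, 0.02 and -0.20, all 4 not called (limma adjusted p = 0.453, 0.163, 0.978 and 0.683). At 72 h, DNMT1 was 7753 in replicate 1 and 17390 in replicate 2 of decitabine. Of 16 genes of the DNA methylation machinery, UHRF1 and TET1 fell, 2 also adjusted over the list alone (camera adjusted p = 0.367). Of 16 decitabine uptake and metabolism genes, the deaminase gene CDA rose from 50.2 ± 4.25 to 181 ± 21.7 and SAMHD1 and SLC29A2 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.125, and 0.0454 without decitabine 72 h replicate 2). EDC4, a scaffold of mRNA decapping, fell from 1292 ± 14.5 to 621 ± 94.2, the 1 call of 20 decapping genes, also adjusted over the list alone (camera adjusted p = 0.227). METTL16, a methyltransferase, fell from 558 ± 211 to 220 ± 17.6, the 1 call of 20 m6A genes, also adjusted over the list alone (median -0.33, camera adjusted p = 0.0125, adjusted p = 0.199 with an estimated correlation and 0.105 with quantile normalisation). Of 11 fits with 1 library left out, the call of UHRF1 was lost in 8. The calls of TET1, SAMHD1 and CDA were each lost in 4 of these fits, and those of METTL16 and EDC4 in 3.

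Metabolic lists and genes of other lineages also changed at 120 h. In the cholesterol synthesis list, 1 of 17 rose and 3 fell, or 1 and 9 adjusted over the list alone (median -0.57, camera adjusted p = 0.000855, adjusted p = 0.192 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell from 2840 ± 366 to 1426 ± 41.9, and the epoxidase gene SQLE from 1794 ± 163 to 1119 ± 23.0. Ribosomal protein genes were lower, with RPL38 as the 1 call of 76 and none adjusted over the list alone (median -0.29, camera adjusted p = 0.00109, adjusted p = 0.464 with an estimated correlation and 0.613 with quantile normalisation). In the stress response list, PSAT1 and SHMT2, of serine and glycine metabolism, fell, 2 also adjusted over the list alone, with a median of 0.25 against a camera direction of lower (adjusted p = 0.61). Among the 7 lymphoid genes tested, CD3D, GNLY and NKG7 rose, 3 also adjusted over the list alone (median 1.35, camera adjusted p = 0.0125, adjusted p = 0.192 with an estimated correlation). Without the filter on low values, 5 of 17 rose (median 1.10, camera adjusted p = 0.0024, adjusted p = 0.0876 with an estimated correlation). CD3D stood at 125 ± 23.7 against 0.293 ± 0.415, and GNLY at 378 ± 35.4 against 1.57 ± 0.109. Among the 6 epithelial and stromal genes tested, LUM and FN1 rose, 2 also adjusted over the list alone (median 1.51, camera adjusted p = 0.0486, adjusted p = 0.268 with an estimated correlation, 0.149 with quantile normalisation, 0.106 without decitabine 72 h replicate 2 and 0.189 without the filter). LUM, a proteoglycan of connective tissue, stood at 220 ± 20.1 against 1.33 ± 1.89.

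In the remaining lists at 120 h, calls were single genes. The retroviral envelope gene ERV3-1 rose and RTL10 fell among 4 tested of 13 endogenous-retrovirus-derived genes, 1 and 1 also adjusted over the list alone (camera adjusted p = 0.72). The nuclear RNA NEAT1 rose from 1520 ± 344 to 4800 ± 119 among 7 structural RNAs, 1 also adjusted over the list alone (camera adjusted p = 0.72). PEG3 fell from 252 ± 1.82 to 111 ± 14.3 among 16 imprinted genes, none adjusted over the list alone (camera adjusted p = 0.815). The 13 mitochondrial mRNAs had a median of -0.38 and no call (camera adjusted p = 0.249), and of HOXA and HOXB genes only 1 was tested, without a call. Of the lowest genes, PALD1 fell from 146 ± 8.72 to 20.1 ± 0.150 and DDN from 93.8 ± 1.64 to 13.2 ± 7.66. ZFP41 and FJX1 fell with log2 fold changes of -3.07 and -2.75. EIF3CL was listed at 0 in both decitabine libraries, with 36.7 and 326 in the DMSO libraries, and shares reads with its near-identical copy EIF3C. Of 11 fits with 1 library left out, the calls of RPL38 and RTL10 were each lost in 8. Those of NEAT1, SHMT2 and PEG3 were each lost in 4, those of EIF3CL, FJX1, SQLE and FN1 in 3, and that of ZFP41 in 2.

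The counts at 120 h varied with the libraries of that time and with the scaling. Limma called 591 genes higher and 207 lower without decitabine 120 h replicate 1, 640 and 249 without its replicate 2, 895 and 336 without DMSO 120 h replicate 1 and 829 and 253 without its replicate 2. It called 2557 and 2392 without decitabine 72 h replicate 1 and 2556 and 2390 without its replicate 2. The share of higher genes among those called was 62.3%, and 50.8% with quantile normalisation, 50.7% with a common median, 53.2% with the GC correction and 51.7 to 76.6% over the left-out libraries. The median log2 fold change of all genes, 0.07, was -0.10 and -0.06 under these scalings, and at 72 h it was 0.09, or -0.04 with quantile normalisation.

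The responses at 72 and 120 h shared most of the genes called at 72 h. Of the 303 genes higher at 72 h, 282 were also called higher at 120 h, against 30 for independent lists, and of the 50 lower, 42 were also called lower, against 3.0. These included EPX, PRG2, S100A12, DAZL, MAEL and COL14A1 among the higher and MYC, IRF8, CCR2 and MS4A6A among the lower. No gene was called in opposite directions. Both sets of calls rest on 1 spread per gene from all libraries, which by itself favours the same genes. In separate fits with no library in common, of 72 h with the 6 h libraries and of 120 h alone, limma called 17 genes higher at 72 h, and all 17 were among the 2328 called higher at 120 h, against 2.5 for independent lists. The 1 gene lower at 72 h was not among the 1924 lower at 120 h. The compared groups had no library in common, and their log2 fold changes correlated across genes, which are not independent replicates, with a Pearson r of 0.61 and a Spearman rho of 0.53.

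The effect of decitabine at both later times was tested against that at 6 h, when cells had received 1 of the 3 additions, so time and the number of additions changed together. The effect of decitabine differed between 72 and 6 h for 99 genes (90 more positive and 9 more negative at 72 h) and between 120 and 6 h for 953 (689 and 264). EPX, DAZL, MAEL and COL14A1 were more positive and MYC more negative at both later times than at 6 h. Between 120 and 72 h limma called 0 single genes, with a smallest adjusted p of 0.276, and 1022 had an unadjusted p under 0.05. As lists, the late neutrophil genes were more positive at 120 than at 72 h by a median of 1.37 (camera adjusted p = 1.23e-15, adjusted p = 0.0289 with an estimated correlation). The NF-kB targets (0.90, camera adjusted p = 0.000117), MHC class I genes (0.66, 0.000728), eosinophil genes (0.60, 0.00122), primary granule genes (0.66, 0.0103) and monocyte genes (0.66, 0.0355) were more positive too. With an estimated correlation their adjusted p were 0.0528, 0.131, 0.0965, 0.426 and 0.383. DNA replication (-0.61, camera adjusted p = 1.2e-09), DNA repair (-0.38, 0.000199), mitotic (-0.35, 0.000894), DNA methylation (-0.43, 0.0475) and mitochondrial genes (-1.35, 0.000658) were more negative. For these the adjusted p with an estimated correlation were 0.131, 0.28, 0.464, 0.426 and 0.464. The mitochondrial difference cannot be told apart from the split by FP671120.7. At 120 h the decitabine and DMSO libraries lay on 1 side of it, whereas decitabine 72 h replicate 1 lay on the other side from DMSO 72 h. All the other list differences between 120 and 72 h compare the same libraries, and how far the split enters them was not tested.

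Those counts also moved with single libraries. For 72 against 6 h, limma called 9 genes without either decitabine 120 h library, 55 without either DMSO 120 h library, 6 and 27 without decitabine 6 h replicates 1 and 2, and 22 and 19 without DMSO 6 h replicates 1 and 2. It called 3741 without decitabine 72 h replicate 1 and 324 without its replicate 2. For 120 against 6 h, limma called 225 without either decitabine 120 h library, 451 and 344 without DMSO 120 h replicates 1 and 2, 301 and 372 without decitabine 6 h replicates 1 and 2, and 327 and 334 without DMSO 6 h replicates 1 and 2. It called 2988 and 2980 without decitabine 72 h replicates 1 and 2. For 120 against 72 h it called 2901 without decitabine 72 h replicate 1, 1 without a trend and 6 with no filter on low values.

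In DMSO alone, no single gene was called between times, and the lists that camera called did not hold with an estimated correlation. Cholesterol synthesis genes were higher at 72 h than at 6 h in 15 of 17 members, with a median of 0.57 (camera adjusted p = 2.72e-13, adjusted p = 0.0545 with an estimated correlation), and at 120 h in 16 of 17, with a median of 0.58 (camera adjusted p = 8.86e-13, adjusted p = 0.0545 with an estimated correlation). HMGCS1 stood at 1550 ± 38.5 at 6 h and 2840 ± 366 at 120 h. The DMSO 120 h libraries are also the controls of decitabine at 120 h, so a high value in them by chance would raise the change with time and lower that with decitabine. All 13 mitochondrial mRNAs were higher at 120 h than at 6 h, with a median of 1.28 (camera adjusted p = 2.72e-13, adjusted p = 0.761 with an estimated correlation), and these times lay on opposite sides of the split by FP671120.7. Ribosomal protein genes were lower at 120 h (camera adjusted p = 0.0255, adjusted p = 0.999 with an estimated correlation and 0.24 with quantile normalisation). Limma called 0 genes at 72 h and at 120 h, with smallest adjusted p of 0.24 and 0.366, and 456 and 865 genes had an unadjusted p under 0.05. Other settings called 116 and 1 genes at these times (no filter on low values), 1 and 1 (no trend), 1 and 3 (sample weights) or, at 120 h, 1 (own spread) and 12 without either decitabine 72 h library.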

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

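The tests of a wrong label and of low depth for decitabine 72 h replicate 2, and those of RNA from other cell types, were chosen only after the result was seen, as were all alternatives described as added later.

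The effect of decitabine differed between times by a test of the difference itself, which is why the following values call for a closer look. For 72 against 6 h, limma called 99 genes, from 6 without decitabine 6 h replicate 1 to 3741 without decitabine 72 h replicate 1, and 18 of them are genes named here, 15 more positive and 3 more negative at 72 h. On the log2 scale the differences of germ-line, histone and other genes were H1-6 6.82, H1-1 6.72, DCAF4L1 7.66, FAM9C 6.75, COL14A1 8.12, MAGEB2 5.19 and MAEL 7.32. That of DCAF4L1 rests on the lone DMSO 72 h library, at 1.49 against 7.98 to 14.5 in the other 4. Those of myeloid and inflammatory genes were EPX 4.10, PRG2 2.05, S100A12 1.75 and CCL2 2.92. The negative differences were MYC -1.87 and MS4A6A -3.41. For genes with a group listed at 0 no size is given. Of these, PNMA5, TKTL1, DAZL and CD3D were more positive at 72 h, at limma adjusted p of 0.012, 0.0187, 0.0372 and 0.0156, and EIF3CL was more negative (0.0472). At 6 h, CD3D was low, at 6.10 and 4.37 with DMSO and 0.21 and 0 with decitabine. The differences of COL14A1 and MAEL also rest in part on low values at 6 h. COL14A1 stood there at 7.99 and 3.87 with DMSO and 1.18 and 2.65 with decitabine. MAEL stood at 1.60 and 1.71 with DMSO and 0 and 0.68 with decitabine. EIF3CL stood at 27.9 and 0 with DMSO and 445 and 310 with decitabine at 6 h.

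For 120 against 6 h, limma called 953 genes, from 225 without either decitabine 120 h library to 2988 without decitabine 72 h replicate 1, and 49 of them are genes named here, 37 more positive and 12 more negative at 120 h. The differences of germ-line, histone and other genes were PNMA5 6.22, H1-6 4.97, H1-1 5.34, H4C4 2.06, DCAF4L1 5.36, FAM9C 7.49, COL14A1 9.60, TKTL1 7.41, MAGEB2 3.87 and MAEL 6.33, and that of the retroviral envelope gene ERV3-1 was 1.40. Those of granulocyte and monocyte genes were EPX 6.27, PRG2 2.90, BPI 2.23, RNASE2 2.63, S100A12 3.12, ITGAM 2.53 and CLEC7A 2.76, and that of ITGA2B was 4.79. Immune and inflammatory genes differed by 4.06 (CCL2), 2.46 (LAMP3), 4.70 (LGALS3BP), 2.91 (TLR8), 4.45 (AIM2) and 1.27 (HLA-C). CDKN1A, BTG2, TP53INP1 and BCL2A1, from the p53 target and apoptosis lists, differed by 2.65, 3.18, 2.98 and 2.94. The lymphoid genes CD3D and GNLY differed by 9.12 and 7.53. That of CD3D rests in part on low values at 6 h, 6.10 and 4.37 with DMSO and 0.21 and 0 with decitabine. So do those of COL14A1 and MAEL. At 6 h COL14A1 stood at 7.99 and 3.87 with DMSO and 1.18 and 2.65 with decitabine. MAEL stood at 1.60 and 1.71 with DMSO and 0 and 0.68 with decitabine. The negative differences were MYC -2.17, IRF8 -2.20, CCR2 -2.50, MS4A6A -2.60, PALD1 -2.63, NTHL1 -1.81, DDN -3.04, EDC4 -1.23, PSAT1 -1.51, SHMT2 -1.06 and HMGCS1 -1.14. With a group listed at 0 and no size given, PAGE2B, GATA1, DAZL, P2RY14, H3C3 and LUM were more positive at 120 h, at limma adjusted p of 0.00593, 0.00724, 0.00276, 0.00159, 0.01 and 0.00932, and EIF3CL was more negative (0.0113). For 2 of these the 6 h values matter. P2RY14 stood at 11.4 and 3.54 with DMSO and at 0 with decitabine, and EIF3CL at 27.9 and 0 with DMSO and 445 and 310 with decitabine. Over all DMSO libraries EIF3CL ranged from 0 to 326.

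Decitabine 72 h replicate 2 lay far from replicate 1, with a median absolute log2 difference of 0.59. Trends with GC content and transcript length were tested, and the difference stayed at 0.542 after their removal against at most 0.260 in the other pairs, which argues against them as the whole cause. A DMSO or 6 h library under this label was argued against by the 1326 genes at least 2-fold higher at 120 h, which lay 1.346 above the DMSO mean in this library and 1.351 in replicate 1 (median log2). Its estimated depth, 23.1 M counts against a median of 18.6 M, argues against low depth. What set these libraries apart stays open, a difference in library preparation included, and no biological explanation was tested.

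Lymphoid and stromal genes rose in a myeloid line, which RNA of other cells in the decitabine libraries could in principle bring. T or NK cells would bring their other abundant transcripts too, yet the median of 13 of these was 2.1 at 120 h against 125 for CD3D, with CD3E at 3.93, TRBC2 at 1.07, GZMA at 0 and PRF1 at 2.1, which argues against them. TRAC (181 against 21.3 in DMSO), NKG7 (261 against 73.7) and IL32 (79.5 against 0) were higher as well. The median of 10 fibroblast transcripts was 0.0211 against 220 for LUM, with COL1A1 at 0.0422, COL3A1 at 0 and SPARC at 8.86, which argues against fibroblasts. Activation of single genes of these lineages by the drug stays open as a hypothesis that was not tested, as do reads shared with related genes.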

How the results depend on the processing

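Sample weights, the GC correction, the comparison with all 5 DMSO libraries, the list tests without decitabine 72 h replicate 2 or single 6 h libraries or with no filter, the separate fits of 72 and 120 h, and the list tests of culture time and of differences between times were chosen after seeing the data, and the other alternatives before. The gene counts are from limma, and where they moved the cause was not tested, unless stated.

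With pseudocounts of 0.5 and 5, at least 50 in at least 2 libraries, or a common median, all counts stayed within 1.5 times those reported (72 h, 251 to 342 higher and 44 to 64 lower; 120 h, 1273 to 1695 and 954 to 1271). Without a filter on low values, 162 genes were lower at 72 h, 589 differed between 120 and 6 h, 6 between 120 and 72 h, and 116 and 1 changed with culture time in DMSO at 72 and 120 h. Quantile normalisation gave 97 lower genes at 72 h and 1465 at 120 h, the GC correction 101 lower at 72 h and a share of higher calls of 75.3%, against 85.8%. Quantile normalisation moved the median difference of all genes from 0.10 to -0.04 between 72 and 6 h and from 0.08 to -0.08 between 120 and 6 h, and a common median moved it from 0.01 to -0.16 between 120 and 72 h. Without a trend, 2 genes were higher and 1 lower at 6 h, 33 lower at 72 h, and 1 gene each was called between 120 and 72 h and with culture time at 72 and 120 h. With the spread of the libraries compared alone, 1 gene was higher at 6 h, 0 were higher and 0 lower at 72 h, where 1 residual degree of freedom is left, 1924 were lower at 120 h, and 1 changed with culture time at 120 h. A threshold of 2-fold beside the adjusted p left 485 lower genes at 120 h, by its construction. Sample weights gave 75 higher and 5 lower at 72 h, 2709 and 2322 at 120 h, 29 and 3021 for the differences from 6 h, and 1 and 3 for culture time. They kept 79 of the 353 calls at 72 h and all 2570 at 120 h. Against all 5 DMSO libraries, 1730 genes were higher and 1187 lower at 72 h, with 334 of the 353 calls kept, and AVIL reversed to a log2 fold change of 0.46 (limma adjusted p = 0.839), since the DMSO 72 h library is high for this gene.

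With a replicate block, 194 genes were higher and 21 lower at 72 h and 53 differed between 72 and 6 h, and other gene counts stayed within 1.5 times. Deviations of libraries with the same number correlated between -0.08 and 0.12 over 10 pairs of groups, so the numbers were not taken to pair the samples. Quasi-likelihood and Wald tests on read counts were not run, as whole reads were not recovered.

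Leaving out 1 library at a time gave 0 to 3 lower and 0 higher genes at 6 h, 130 to 2689 higher and 13 to 2070 lower at 72 h, and 591 to 2557 and 207 to 2392 at 120 h. It gave 6 to 3741, 225 to 2988 and 0 to 2901 for the differences of 72 from 6 h, 120 from 6 h and 120 from 72 h, and 0 and 0 to 12 for culture time at 72 and 120 h. All highest values came without a decitabine 72 h library except at 6 h, where it was decitabine 6 h replicate 2. Without decitabine 72 h replicate 2, 305 of the 353 calls at 72 h and all 2570 at 120 h were kept. Without DMSO 72 h replicate 1 no value could be had at 72 h, so no left-out fit tests how far that library matters. Of the 40 calls at 72 h among genes picked by the naming rule, 19 were lost with sample weights. All 40 were lost with the spread of the 72 h libraries alone. Of the genes picked by the naming rule, 51 of 75 calls at 120 h and 28 of 40 at 72 h held in every left-out fit.

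The lists called were 4, 11 and 17 at 6, 72 and 120 h. With an estimated correlation in camera they were 0, 3 and 4, with the directional fry test 0, 13 and 20, with the mixed fry test 0, 21 and 26, and with no filter on low values 2, 12 and 18. Calls gained with no filter were the mitotic (camera adjusted p = 0.02) and mitochondrial lists (0.0372) at 72 h, both higher, and at 120 h the p53 targets, higher (0.0305), and decitabine uptake and metabolism, lower (0.0336). With an estimated correlation their adjusted p were 0.602, 0.657, 0.187 and 0.187. A single count was worth 0.407 to 0.961 normalised units, which limits the precision of genes with few counts.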

Other observations

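The tests of mitochondrial mRNAs and the split of the chromosome tests by level in DMSO were chosen only after the result was seen, and the test of chromosome X before.

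Among tested genes under 10 in all DMSO libraries, those of chromosome X were called higher with decitabine more often than those of other chromosomes. Low genes that stayed under the filter with decitabine were not tested, so this is no rate over all genes low in DMSO. Over all tested genes at 120 h, limma called 75 of 504 tested X genes higher (14.9%), against 9.8% of the others (Fisher's exact test, two-sided, adjusted p = 0.00829 over the chromosomes), and at 72 h 30 (6.0%) against 1.7% (adjusted p = 5.56e-07). Among them were PNMA5, FAM9C, TKTL1, MAGEB2, PAGE2B, GATA1 and TLR8. Genes under 10 in all DMSO libraries could enter the test only through their decitabine libraries, on every chromosome. Among these, 29 of 46 X genes were higher at 120 h (63.0%) against 34.0% of the others (adjusted p = 0.0025), and 34.8 against 9.0% at 72 h (8.05e-05). Among genes at 10 or more in a DMSO library, 46 of 458 X genes and 8.3% of the others were higher at 120 h (adjusted p = 0.352) and 3.1 and 1.3% at 72 h (0.132), so the hypothesis that X genes in general rise more often stays open. Genes with close copies, such as cancer-testis antigens, are not independent in these tests. Chromosome 6, which carries the MHC and the large histone cluster, also had more higher genes at 120 h (112 of 854, 13.1%, Fisher adjusted p = 0.0253). At 120 h this held in neither class alone (0.322 at 10 or more in a DMSO library and 0.136 below). At 72 h chromosome 6 was not called over all tested genes (0.447). In the class below 10 it was, with 12 of 51 genes higher (23.5%) against 9.5% of the others (0.0426). Of 12264 protein-coding genes tested, 11.1% were higher and 7.3% lower at 120 h, and of 2249 long non-coding genes 7.3% and 1.3%.

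Mitochondrial mRNAs were higher at 120 h than at 6 h in DMSO, by a median of 1.28 on the log2 scale. The decitabine 72 h libraries, of 1 age, differed by 1.669, but as a single pair of another treatment they do not exclude culture time as the whole cause. The libraries fell into 5 with FP671120.7 as the top transcript and 6 without, and with this side as a term the DMSO difference was 0.127, but only 1 group had libraries on both sides, so time and a possible preparation batch cannot be told apart. No biological explanation other than culture time was tested.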
